A study of Mus musculus with 2 samples.

How the data were processed

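Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 monomethylated at lysine 4 (H3K4me1), a modification known to mark enhancers and the flanks of active promoters. The tissue was heart from mouse embryos of strain B6NCrl at embryonic day 11.5, pooled over males and females. The labels give 1 group with 2 biological replicates; 109 embryos were pooled for replicate 1, and the labels state no number for replicate 2. No other group was analysed here, so the comparisons are between the replicates and between parts of the genome within them. No control library was analysed here, although the labels name a possible control.

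Each replicate had its own peak list, and 2 further lists covered the series. Per the descriptions deposited with the samples, 1 of these was called on the alignments of both replicates together (the joint list) and the other held replicated peaks derived from the joint list and the replicates' lists (the replicated list). The signal of each peak is the authors' own enrichment value, on a scale not given in the sources used here. The −log10 p and −log10 q of each peak are likewise the authors' values, as deposited. These values are the authors' and were used only to rank or filter peaks within a list. The aligner, the peak caller and the thresholds are not given in the sources used here; the smallest −log10 p in the lists lay between 2.02 and 2.03, and the smallest −log10 q of the replicated list was 0.548. Read depth is unknown from peak lists, so no sensitivity to weak marks can be stated, and a place without a peak is one where none was called.

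Coordinates are those of the mouse assembly mm10 that the deposited lists use, given from 1. Sequence came from GRCm38 patch 6, the same assembly, and genes from GENCODE release 21 for mouse, with 21911 protein-coding genes after keeping 1 gene per symbol. Every peak lay inside the chromosomes of this reference.

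The replicated list gave the main values. The same measure in each replicate's own list gave the error, written as the replicates' mean ± SD with n = 2 after the value of the replicated list; because the replicated list holds fewer peaks than either replicate, its value can lie outside the replicates' values. Peaks overlapped when they shared at least 1 base (bedtools 2.31.1), with 95% Wilson intervals that cover counting error only, since neighbouring peaks are not independent. Chance overlap came from 10 random placements of replicate 1's peaks. Covered bases were assigned to promoters (within 1 kb of a 5' end), exons, introns or intergenic DNA, in that order, and compared with 100 random placements of the peaks on their own chromosomes outside assembly gaps. These classes used all 55413 annotated genes, protein-coding or not, as did the choice of distal peaks. Around 5' ends of protein-coding genes, the share of genes with a peak was taken every 100 bases out to 10 kb, and the highest share within 3 kb was divided by that at the 5' end. A 5' end was CpG-rich when the 250 bases to either side had over 55% GC and an observed over expected CpG ratio above 0.65.

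Coverage near a gene was the percent of bases within 50 kb of its 5' end that peaks covered. For each of 20 fixed gene lists, the median was ranked among 10000 random lists of protein-coding genes of the same length deciles; a list was called high or low when at most 2.5% of random lists lay beyond it. Such ranks describe these libraries across genes, which are not replicates, so no p-values are given across genes or peaks. Hox genes were compared within 5 kb of the 5' end. Peaks at most 1 kb apart were joined into domains, and genes with a 5' end within 50 kb of the 500 domains with the most covered bases were counted. For 18 consensus sequences of transcription factors, the share of 500-bp windows with a match was compared between the centres of distal peaks (over 2.5 kb from any 5' end) and windows 5 kb to either side that touched no peak, and the log2 ratio was ranked among up to 200 shuffles of the consensus. The background windows were not required to lie far from a 5' end. Under the alternatives, the ranks of the log2 ratios came from a random sample of 20000 windows of each kind, while the ratios used every window.

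The gene lists, the consensus sequences, most tests and most alternatives were fixed before the data were examined. So was the rule for named genes: in each list the 3 genes with the highest coverage and the 1 with the lowest, the 10 highest of all genes, the 10 largest domains, the 10 peaks of highest signal, every consensus, and the highest and lowest Hox gene of each group. Genes named outside this rule are said to be so. The alternatives fixed in advance were each replicate alone, the joint list, peaks with −log10 q of at least 5, peaks at or above the median signal, other window sizes and overlaps, other matching of random lists, peak numbers in place of covered bases, other domain definitions, a central 200-bp window and a background 20 kb away. Added after seeing the data were autosomal genes only, matching on CpG-rich 5' ends or on the GC content of the window, 1 gene per shared window, shuffles of a consensus with as many CG dinucleotides, enrichment within GC deciles, random placement within GC deciles, and X genes matched to autosomal genes. Random lists matched on GC content were no longer matched on gene length, while those matched on CpG-rich 5' ends were. The 22 gene families of the closing section, and its tests of peak joining and of GC content, were chosen after the data had been seen. The families were defined by symbol before their coverage was computed.

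The statistics were tested on simulated data. Of 200 random lists of genes left unchanged, 3.5% were called high and 2.0% low; with coverage raised 2-fold 37.5% were called high, and with 4-fold 78% were. A promoter ratio planted at 3.44 was recovered as 3.44, and MEF2 sites planted at a log2 ratio of 2.01 over 20000 windows were recovered at 2.00. Both planted values were computed with the same background as the recovered ones, so they check the arithmetic only. The MEF2 windows were random sequence, without the GC difference of the real windows. A ratio of X to matched autosomal genes planted at 0.3 over 948 genes was recovered as 0.271. That simulation matched genes on length only, and not on CpG-rich 5' ends or GC content as the result itself did. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots matplotlib 3.10.9.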

Results

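H3K4me1 was mapped in hearts of mouse embryos at embryonic day 11.5, when the looped heart tube is forming chambers, valves and an outer epicardial layer. The 2 biological replicates, each a pool of embryos of both sexes, gave 176935 and 185779 peaks that covered 78.2 Mb and 76.0 Mb of the genome. The list called on both replicates together held 146267 peaks (75.3 Mb). The replicated list, on which the values below rest, held 116902 peaks with a median width of 424 bp that covered 67.9 Mb, 2.49% of the genome. Read numbers are unknown from these lists.

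The first comparison was between the replicates. Strong peaks were nearly always overlapped by some peak of the other replicate, strong or weak, and weak ones about as often as not. Of the replicate 1 peaks, 65.6% were overlapped by a replicate 2 peak (95% Wilson interval 65.3% to 65.8%), and 64.7% of replicate 2 peaks by a replicate 1 peak (64.5% to 64.9%), against 5.87% after random placement. Among the decile of peaks with the highest signal, the shares were 96.3% and 95.9%, and among the weakest decile 48.3% and 49.6%. Both replicates covered 45.1 Mb in common, 57.6% of the bases of replicate 1 and 59.3% of those of replicate 2. Across the 21911 protein-coding genes, coverage within 50 kb of the 5' end correlated between replicates with a Spearman rho of 0.982 and a Pearson r of 0.987; genes are not independent replicates. Demanding that 50% of both peaks be shared lowered the overlap to 35.5% and 33.8%. With only peaks of −log10 q of at least 5 kept in both lists, it was 52.2% and 56.3%.

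**Figure D1:**
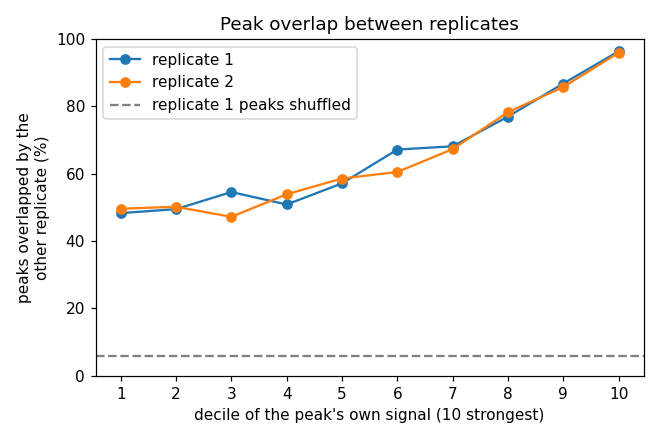
Percent of each replicate's peaks overlapped by at least 1 base in the other replicate (y axis) by decile of the peak's own signal within its list (x axis). Points are replicates, and the dashed line is the mean of 10 random placements of replicate 1 peaks (5.87%); the strongest decile reached 96.3% and 95.9%.

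The next question was where in the genome the mark lay. Introns held 64.0% of covered bases (replicates 62.8% ± 0.933, SD, n = 2), intergenic DNA 19.3%, promoters 9.93% and exons 6.84%. Against random placement, promoters were covered 2.49 times as much (2.35 and 2.56 times in the replicates), introns 1.51 times and intergenic DNA 0.390 times, all beyond each of 100 placements. Peak centres lay a median of 11.9 kb from the nearest 5' end of any annotated gene, protein-coding or not, and 54.0% lay over 10 kb away. The ratios depended on base composition: with placement within GC deciles the promoter ratio was 1.60, and the exon ratio went from 1.64 to 0.995, within the range of placements.

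All of the 10 peaks with the highest signal were centred in introns. Of these, 3 lay in Gse1, which encodes a coiled-coil protein of a histone demethylase complex, and the strongest of all was among them (chromosome 8, 120510466 to 120512800, signal 12.9). An intron of Ahdc1 held a single peak of 13801 bp (chromosome 4, 133039944 to 133053744, signal 12.6). Others lay in Mical2, a monooxygenase of actin (chromosome 7, 112287723 to 112290988), in Prrc2b, in Piezo1, a mechanically gated ion channel, in Mmp15, a membrane-bound matrix metalloproteinase, and in Zfpm1, a partner of GATA factors (chromosome 8, 122294403 to 122295810). The remaining peak lay in Fam178b, 22.4 kb from the 5' end of Sema4c (chromosome 1, 36579193 to 36582321).

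Around the 5' ends of genes the mark formed 2 flanks with a gap between them. A peak lay over the 5' end itself in 7.18% of protein-coding genes, over the position 1000 bases downstream in 20.2%, and over that 700 bases upstream in 11.5%. The ratio of the highest flank to the 5' end was 2.81 (2.41 in replicate 1 and 2.72 in replicate 2). The gap belonged to the 9054 genes with a CpG-rich 5' end, where coverage rose from 4.44% at the 5' end to 35.1% at 1100 bases downstream, a ratio of 7.90 (5.57 and 7.77 in the replicates). At the 12857 other genes the ratio was 1.09. In the small lists of sarcomere and cardiac transcription factor genes the higher flank within 3 kb lay upstream, a difference that was not tested: 50% of the 20 sarcomere genes had a peak 800 bases upstream, and 50% of the 16 transcription factor genes 1200 bases upstream. With −log10 q of at least 5 the higher flank of the transcription factor genes lay downstream (25% at 3000 bases, against 18.8% upstream). None of 18 housekeeping genes had a peak over the 5' end in the replicated list, while 50% had one 1800 bases downstream. Of 1134 olfactory receptor genes, 0.706% had any peak within 3 kb, against 56.5% of all genes. With peaks of −log10 q of at least 5 the ratio over all genes was 4.45. It was 16.35 at genes with a CpG-rich 5' end and 1.41 at the other genes.

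**Figure D2:**
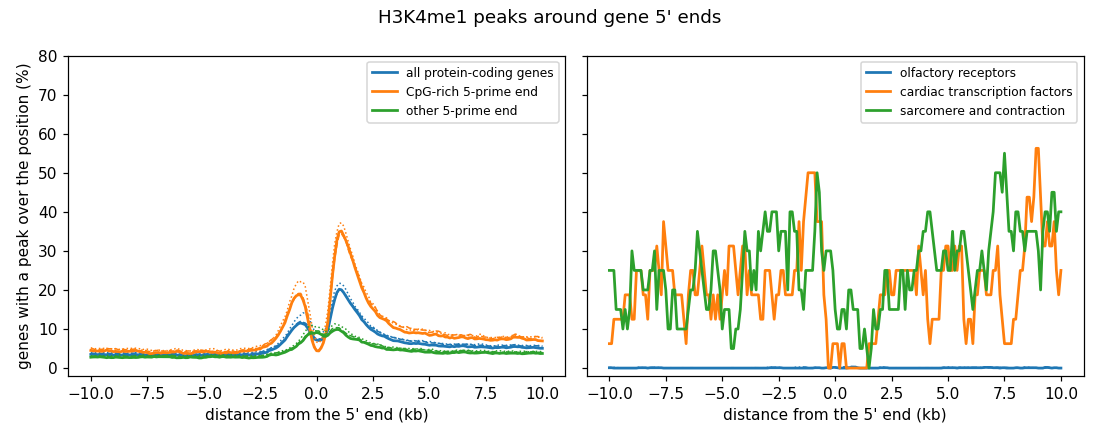
Percent of genes with an H3K4me1 peak over each position (y axis) from 10 kb upstream to 10 kb downstream of the 5' end (x axis). Solid lines are the replicated list, dotted lines replicate 1 and dashed lines replicate 2 (the replicates are not drawn for the lists of 16 and 20 genes); genes with a CpG-rich 5' end fell to 4.44% at the 5' end between higher flanks.

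Cardiac transcription factor and sarcomere genes were high when coverage was measured within 50 kb of the 5' end, while chamber myocardium genes were not (percentile 59.3). The median over all protein-coding genes was 2.44%, with 23.5% of genes at 0. Cardiac transcription factor genes had a median of 13.8% (replicates 14.9% ± 0.163, SD, n = 2), 12 of 16 lying above the upper quartile of all genes, and sarcomere genes 15.3% (16.4% ± 0.733), 16 of 20 lying above it. For both lists, 0 of 10000 random lists reached as high. Gata5 (30.6%, replicates 32.4% ± 0.771, chromosome 2, 180325133 to 180334699) and Gata4 (27.6%, replicates 27.8% ± 0.940, chromosome 14, 63198922 to 63271692), zinc finger factors of early heart formation, and Myocd, a coactivator of SRF (21.7%, replicates 22.9% ± 0.825), were the highest among the transcription factors, and the methyltransferase gene Smyd1 the lowest at 0.479%. Among sarcomere and contraction genes, the neighbouring troponin genes Tnni1 (37.9%, replicates 38.1% ± 0.973) and Tnnt2 (33.5%, replicates 33.3% ± 1.30) share part of their windows on chromosome 1, and the calcium release channel gene Ryr2 followed at 28.1%; Ttn, which encodes titin, was lowest at 1.20%. With 1 gene per shared window, both lists stayed above every random list.

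Targets of developmental signalling pathways were also high, with a median of 9.11% (9.63% ± 0.710) that 4 of 10000 random lists reached. The inhibitors of BMP and TGF-beta signalling Smad6 (50.5%, replicates 50.2% ± 1.31, chromosome 9, 63953076 to 64022059) and Smad7 (38.8%, replicates 38.8% ± 0.558) led, with Id3, a target of BMP signalling, at 22.9%; Rarb, the retinoic acid receptor beta gene, was at 0. Housekeeping genes were high at 6.95% (7.58% ± 0.290; 149 of 10000 as high), led by Rplp0 (23.1%), Ywhaz (17.4%) and Vcp (13.6%), with the X-linked Pgk1 at 0.262%. The housekeeping call was lost when random lists were matched on a CpG-rich 5' end (percentile 94.6) or on the GC content of the window (94.8).

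The other heart lists, chamber myocardium included, did not pass the threshold, although single genes in them were heavily marked. Some were high under single alternatives: pacemaker genes under 3 (percentiles 97.8 to 99.2), second heart field (99.4) and cushion genes (98.5) within 20 kb, and smooth muscle genes with CpG matching (97.7). Pacemaker and atrioventricular canal genes had a median of 6.35% (percentile 96.5), with Gjd3 (32.7%), the pacemaker channel gene Hcn4 (23.5%, replicates 24.1% ± 1.45) and Cacna2d2 (21.4%) highest and Hcn1 lowest (0.961%). Endocardium and endothelium genes had 4.70% (percentile 94.3), led by Notch1 (27.0%, replicates 26.2% ± 2.36), Fli1 (14%) and Pecam1 (12.3%), with Emcn at 0.241%. Smooth muscle genes had 6.09% (percentile 93.4), led by the intermediate filament gene Des (32.2%, replicates 32.2% ± 1.14), Smtn (13.7%) and Tagln (7.85%), with Myh11 at 0.857%. Second heart field and outflow tract genes had 4.59% (percentile 88.3), led by Wnt11 (30.4%, replicates 30.6% ± 0.192), Hand2 (13.8%) and Foxc2 (13.5%), with Eya1 at 0. Cushion and valve mesenchyme genes had 3.25% (percentile 71.3), led by Snai1 (20.3%), Scx (16.2%) and Meox1 (14.5%), with Snai2 at 0. Chamber myocardium genes had 2.66% (percentile 59.3), led by Bmp10 (11.7%), Scn5a (11.2%) and Irx5 (6.88%), with the X-linked Smpx at 0. Epicardium genes had 2.25% (percentile 45.9), led by Msln (10.1%), Upk3b (9.77%) and Wt1 (5.17%), with Sema3d at 0.

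Among lists of other tissues, epidermis genes were low: 8 of 12 were at 0, and the median of 0 lay at percentile 0.98. Grhl1 (5.07%), Dsg3 (2.90%) and Krt14 (1.07%) were the highest of them, and Trp63 was at 0. The call was lost with replicate 2 alone (percentile 5.02) and under 4 other alternatives. Skeletal muscle genes had 6.03% and percentile 97.0, short of the threshold, led by the neighbours Tnnt3 (39.6%) and Tnni2 (23.2%) and by Mymk (17.9%), with Myf6 at 0.233%; matching on GC content put that list at percentile 36.5, and 6 other alternatives put it past the threshold, at 98.0 to 99.6. Metabolic genes of mitochondria and fatty acid use had 3.91% (percentile 78.5; Ppargc1a 16.1%, Esrra 13.8%, Fabp3 8.37%, Pdk4 0.824%). Limb and craniofacial genes had 3.78% (percentile 76.7; Lmx1b 9.69%, Alx3 8.26%, Tbx4 7.89%, Alx1 0.419%). Blood genes had 3.17% (percentile 69.4; Csf1r 13.1%, Spi1 13%, Epor 7.51%, Ptprc 0). Neural genes had 2.70% (percentile 62.2; Tubb3 7.78%, Gfap 6.23%, Pax6 5.60%, Elavl4 0.204%). Liver and gut genes had 2.16% (percentile 42.8; Apoa2 13.1%, Apoa1 8.61%, Hnf1a 8.13%, Serpina1a 0). Neural crest genes had 1.97% (percentile 33.5; Ngfr 13.7%, Ets1 9.34%, Sox10 8.99%, Tfap2b 0). Lymphocyte genes had 1.12% (percentile 14.4; Cd4 12.7%, Cd79b 7.28%, Lck 6.84%, Rag2 0). Coverage rose with the GC content of the window across genes (Spearman rho 0.753), and matching on it left the cardiac transcription factor, sarcomere and signalling lists at percentiles 100, 100 and 99.9.

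**Figure D3:**
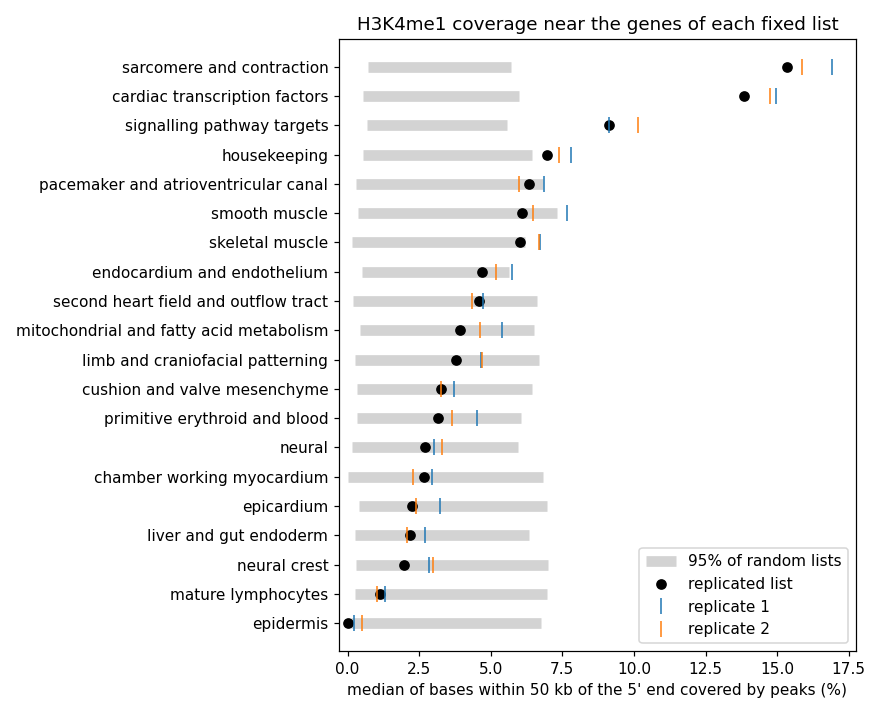
Median percent of bases within 50 kb of the 5' end covered by peaks (x axis) for each of the 20 fixed lists (y axis). Black points are the replicated list, coloured ticks the replicates and grey bars the middle 95% of 10000 random lists matched on gene length; cardiac transcription factors (13.8%), sarcomere genes (15.3%), signalling targets (9.11%) and housekeeping genes (6.95%) lie above their bars.

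Of all protein-coding genes, Zmiz1, which encodes a transcriptional coactivator, had the highest coverage (58.7%, replicates 57.3% ± 0.475; chromosome 14, 25459185 to 25666743). It was followed by Zfpm1 (54.2%, replicates 53.9% ± 1.64), Ahdc1 (50.9%, replicates 49.4% ± 0.684), Smad6, the IGF2 receptor gene Igf2r (49.7%, replicates 47.9% ± 2.73), Mical2 (46.9%, replicates 45.8% ± 0.600), the paired basement membrane collagen genes Col4a1 and Col4a2 (46.2%, replicates 47.5% ± 2.09 over a shared window), Smad3, a TGF-beta effector (46.0%, replicates 46.3% ± 2.38), and Mrpl23 (45.8%, replicates 45.8% ± 1.07), a neighbour of Tnnt3 on chromosome 7.

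Peaks were also joined into domains across gaps of up to 1 kb. Zmiz1, Zfpm1, Smad6 and Mical2, among the 10 highest genes, were also among the 10 largest domains; the overlap was not tested. The largest of 70525 domains lay in Zmiz1 and held 61.9 kb of covered bases (chromosome 14, 25461177 to 25528022). Next came Zfpm1 (45.3 kb), Smad6 (40.5 kb), the netrin receptor gene Unc5b (36.2 kb), Mical2 (33.0 kb), a pair in Gse1 whose nearest 5' end is that of Gins2 (31.2 kb and 28.0 kb), Sipa1l2 (26.8 kb), the corepressor gene Ncor2 (26.5 kb) and Creb3l2 (26.3 kb). The 500 largest domains lay within 50 kb of 657 genes. These included 5 of 20 sarcomere genes (Myl7, Actn2, Tnnt2, Tnni1 and Ryr2, against 0.638 in random lists, percentile 99.96), 3 of 16 cardiac transcription factor genes (Gata4, Gata5 and Gata6, against 0.528, percentile 99.1) and 5 of 24 signalling targets (Nkd1, Ptch1, Smad6, Smad7 and Id1, against 0.799, percentile 99.95). The other 17 lists were not called. The members of the called lists were named without regard to the rule for named genes. The neighbours Tnni1 and Tnnt2 count here as separate members. Neither matching on GC content nor 1 gene per shared window was applied to domains. The counts use the same peaks and the same distance of 50 kb as the coverage near genes, so they partly repeat it. With peaks of −log10 q of at least 5, the transcription factor and sarcomere lists fell to percentiles 95.2 and 92.5, and with gaps of up to 3 kb the signalling list fell to 96.8.

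Hox genes, which pattern the body axis, had their highest pooled median in the middle paralog groups, though not in every cluster. The outermost annotated 5' end was used, which put some Hox genes beside another paralog. Hoxc5 (chromosome 15, from 102967443) was scored almost in the window of Hoxc10 (from 102966796), with the same values. Hoxd3 and Hoxd4 (chromosome 2, from 74711927 and 74711929) shared nearly the same window, which reaches the end of Hoxd8 (74707933). Hoxa3 (chromosome 6, 52169062 to 52213336) was scored at its far end, beside Hoxa6 (to 52208722). The medians of paralog groups 1 to 4, pooled and in Hoxa and Hoxd, thus rest partly on genes scored beside paralog groups 5 to 8. The median within 5 kb of the 5' end was 6.89% for the 12 genes of paralog groups 1 to 4 (replicates 8.92% ± 1.24, SD, n = 2), 11.6% for the 11 of groups 5 to 8 (10.7% ± 0.389) and 2.99% for the 16 of groups 9 to 13 (4.44% ± 0.339). In the replicated list, Hoxb2 (21.2%; 22.3% in replicate 1 and 22.4% in replicate 2), Hoxa6 (19.1%; 20.9% and 21%) and Hoxd13 (10.5%; 2.80% and 11.9%) were the highest of their groups. Hoxd4, tied with Hoxd3 (2.62%; 4.83% and 0), Hoxc8, tied with Hoxc5 (0; Hoxc8 0 in both replicates), and Hoxa13, tied with several others (0; 7.59% and 1.93%), were the lowest. Values of some single Hox genes thus differed widely between the replicates. By cluster, the medians of groups 1 to 4, 5 to 8 and 9 to 13 were 10.4%, 13.2% and 4.62% in Hoxa and 5.96%, 9.94% and 2.33% in Hoxb. In Hoxc they were 6.61% (1 gene), 0 (2 of 3 genes at 0, Hoxc5 among them) and 2.81%. The median of 0 in Hoxc thus rests partly on a gene scored beside Hoxc10. For Hoxd the medians were 2.62%, 8.33% (1 gene) and 2.03%. In Hoxd the order of groups 1 to 4 and 9 to 13 differed between the replicates (4.83% and 2.80% in replicate 1, 0 and 6.81% in replicate 2). No difference between groups was tested. The pooled median of groups 1 to 4 exceeded that of groups 9 to 13 by 2.29 percentage points with peaks at or above the median signal and by 0 with −log10 q of at least 5, but by 6.90 within 2 kb of the 5' end and by 5.59 in replicate 1 alone.

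Distal peaks were compared with neighbouring DNA, which could itself lie near 5' ends, for the sites of transcription factors. Sites of MEF2, GATA and TEAD factors were enriched beyond every shuffle of their letters. The MEF2 consensus CTAWWWATAG (W for A or T), bound by factors that switch on muscle genes, was present in 1.79% of 89330 peak windows and 0.584% of 137801 background windows, a log2 ratio of 1.62 (replicates 1.42 ± 0.14, SD, n = 2). The TEAD consensus GGAATGY (Y for C or T), bound by effectors of the Hippo pathway, was present in 16.6% and 11.2% (log2 ratio 0.56; 0.49 ± 0.01), narrowly above its highest shuffle (0.55), and the GATA consensus AGATAA in 29.8% and 24.3% (0.29; 0.25 ± 0.02, ranked among only 29 distinct shuffles). The NKX2-5 consensus was slightly enriched (log2 ratio 0.12, percentile 98.0), as was that of AP-1 (0.27, percentile 99.0). Peak windows were richer in GC than the background (48.9% against 45.1%); within GC deciles the log2 ratios were 2.29 for MEF2, 0.64 for GATA and 0.55 for TEAD, and AP-1 fell to percentile 95.5. NKX2-5 fell to percentiles 96.5 with the joint list and 97.0 with stricter peaks.

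The other consensus sequences were within the range of their shuffles. Of heart factors, TBX had a log2 ratio of 0.06 (percentile 53.0), the HAND E-box 0.10 (44.7) and SRF 0.04 (72.5). ETS had 0.59 (86.5, replicates 0.39 ± 0.14), SOX −0.04 (60.5) and FOX 0.03 (96.0). CTCF had 0.28 (31.5, replicates 0.43 ± 0.03) and p63 0.10 (58.5). Of factors of other tissues, HNF1 had −0.52 (96.0), HNF4 0.07 (61.5), NEUROD 0.03 (11.5) and PAX6 0.50 (96.5). REST had 0.21 (91.5), a value that rests on 6 matching peak windows.

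**Figure D4:**
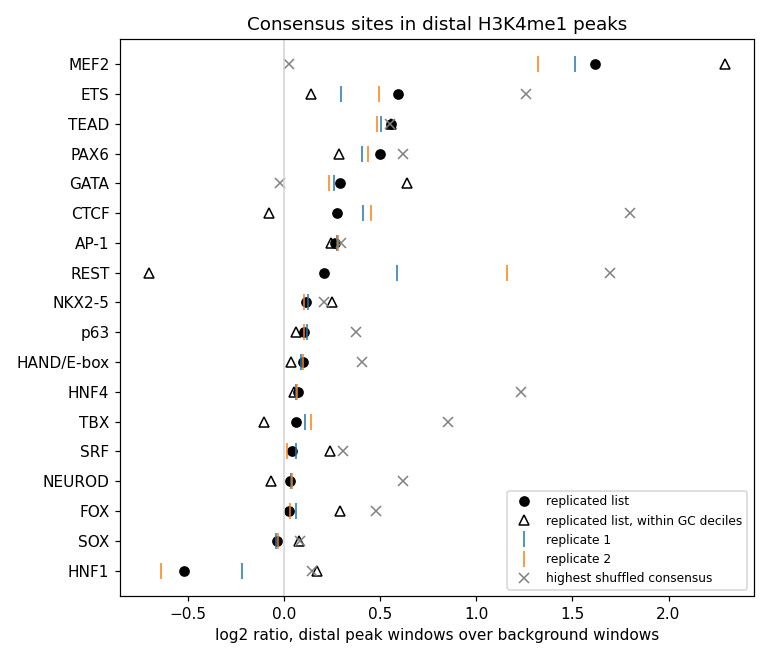
Log2 ratio of the share of distal peak windows to the share of background windows with each consensus (x axis, consensus by name on the y axis). Circles are the replicated list, triangles the same within GC deciles, ticks the replicates and crosses the highest shuffle; MEF2 (1.62), TEAD (0.56) and GATA (0.29) lie beyond their crosses, TEAD narrowly (0.55).

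Chromosomes differed in how much of them was marked, and the X chromosome stood apart. Peaks covered 2.83% of the autosomes, from 1.91% of chromosome 3 to 4.70% of chromosome 11, but 0.0943% of the X chromosome. The ratio of X to autosomes was 0.0333 (0.0524 ± 0.00668 in the replicates, n = 2). In peaks per protein-coding gene, the X had 0.435 and the autosomes 5.61. The Y chromosome had 0 peaks in every list. The X-linked genes Smpx and Pgk1, the lowest of their lists, lie on this chromosome. With −log10 q of at least 5 the ratio was 0.0116.

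**Figure D5:**
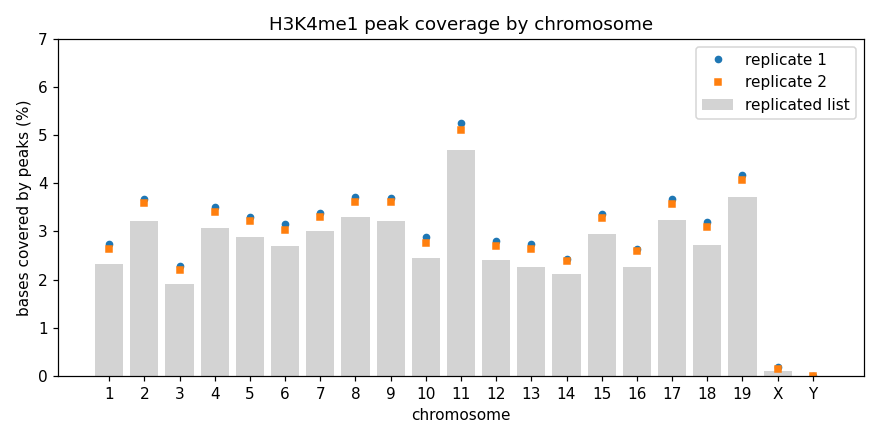
Percent of bases outside assembly gaps that peaks cover (y axis) on each chromosome (x axis). Bars are the replicated list and points the replicates; autosomes range from 1.91% to 4.70%, and X has 0.0943%.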

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

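Most results kept their side of the threshold. Cardiac transcription factor and sarcomere genes were high in coverage under every alternative run, as were MEF2, GATA and TEAD sites. Alternatives that match on CpG-rich 5' ends or GC content, restrict to GC deciles, keep 1 gene per window or match X genes were chosen after seeing the data. Unknown read depth limits what weak peaks can show, and the causes of the changes below were not tested. No paired analysis was possible because the series has 1 group.

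Requiring 50% reciprocal overlap gave 35.5% of replicate 1 and 33.8% of replicate 2 peaks shared; peaks with −log10 q of at least 5 gave 52.2% and 56.3%, and the 50000 strongest of each list 53.2% and 54.8%, since a strong peak can meet one left out of the other list. With placement within GC deciles the exon ratio was 0.995. The flank ratio at 5' ends was 4.45 with −log10 q of at least 5 and 3.28 with peaks at or above the median signal, and ranged from 2.41 to 2.72 with a replicate left out. The ratio of X to autosomes in percent of bases covered ranged from 0.0477 to 0.0572 with a replicate left out. It was 0.0116 with −log10 q of at least 5 and 0.0241 with peaks at or above the median signal. The ratio for matched genes, 0.0924, is one of coverage within 50 kb of 5' ends, a different measure.

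Gene lists that lost their call were housekeeping genes, at percentile 93.8 within 100 kb, 96.2 by peak number, 94.6 with CpG matching and 94.8 with GC matching, and epidermis genes, at 12.5 with −log10 q of at least 5, 3.55 at or above the median signal, 3.85 within 20 kb and 4.94 with CpG matching; without a replicate the latter ranged from 1.48 to 5.02. Lists that gained a call were skeletal muscle (98.0 with the joint list, 99.6 within 20 kb, 99.1 within 100 kb, 98.9 matched on the number of 5' ends, 98.2 by peak number, 99.5 with CpG matching), pacemaker and atrioventricular canal (97.8 with −log10 q of at least 5, 98.7 within 100 kb, 99.2 matched on the number of 5' ends), second heart field (99.4 within 20 kb), cushion and valve mesenchyme (98.5 within 20 kb), smooth muscle (97.7 with CpG matching) and, as low, lymphocytes (1.21 with GC matching).

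The difference in Hox coverage between groups 1 to 4 and 9 to 13 was 0 with −log10 q of at least 5, 2.29 at or above the median signal and 6.90 within 2 kb, and ranged over 3.37 to 5.59 with a replicate left out. Its rho with the paralog number was −0.18 with −log10 q of at least 5 and −0.27 within 2 kb, and ranged over −0.43 to −0.34 with a replicate left out. Near large domains, cardiac transcription factors fell to percentile 95.2 with −log10 q of at least 5 and 94.9 at or above the median signal, sarcomere genes to 92.5 and 92.2, and signalling targets to 96.8 with gaps of 3 kb; pacemaker genes rose to 99.7 with −log10 q of at least 5 and 99.5 with gaps of 3 kb.

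Among consensus sequences, NKX2-5 fell to percentile 96.5 with the joint list and 97.0 with each stricter set of peaks; AP-1 to 95 at or above the median signal, 89.0 in the central 200 bp and 95.5 within GC deciles, with a range of 97.0 to 98.5 when a replicate was left out; PAX6 rose to 99.5 in the central 200 bp, with a range of 76.0 to 98.0 when a replicate was left out. REST moved from 91.5 to 2.0 at or above the median signal and 0 with the background 20 kb away, on 6 matching windows in the whole replicated list. It ranged from 48.25 to 49.75 when a replicate was left out, and no alternative put it above 57.5.

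With GC matching, ribosomal protein genes went from high to percentile 49.0, and olfactory and vomeronasal receptor genes from low to percentile 50. Among 89 named genes, coverage was lower in 76 with −log10 q of at least 5 and in 74 at or above the median signal, by construction. It was higher in 73 with the joint list, also by construction, since every replicated peak is in that list.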

Other observations

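The gene families, which were not among the lists fixed in advance, and the tests of peak joining and of GC content were chosen after the data had been seen. Gene families defined by symbol differed widely in coverage within 50 kb of the 5' end. T-box factor genes had a median of 8.51% (percentile 99.7 among random lists; Tbx2 19.6%, Tbx5 18.5%, Tbx1 13%) and GATA factor genes 13.3% (99.8), where Gata6 had 18.4% and the erythroid gene Gata1, on the X, had 0. The fixed lists already held Gata1, Gata4, Gata5 and Gata6 and several T-box genes, Tbx1, Tbx2 and Tbx5 among them, so these calls partly repeat those of the lists. Integrin genes had 6.08% (99.7; Itga5 17.9%), core histone genes 4.43% (99.98, many in shared windows), and these 4 families stayed high with GC matching and with CpG matching. Semaphorin genes (7.28%, percentile 99.6; Sema3b 32.7%, Sema4c 29.2%), ephrin and Eph receptor genes (7.41%, 99.8; Efna2 29.5%, Epha2 23.1%) and ribosomal protein genes (5.22%, 99.98; Rps14 30.6%) were high, but with GC matching lay at percentiles 96.6, 93.3 and 49.0. Kruppel-like factor genes were high (7.27%, 99.0), and lay at 94.7 with CpG matching.

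Olfactory receptor genes (970 of 1092 with numbered symbols at 0) and vomeronasal receptor genes (312 of 326 at 0) had medians of 0, below every random list; with GC matching both lay at percentile 50, but those random lists are drawn from pools of GC-poor windows that include the receptor genes themselves, so the matching decides little. Zfp genes were low at 1.22% and stayed low with GC matching (percentile 0.01). Members of a family that share windows were ranked as separate genes, since 1 gene per shared window was not run for families. Family percentiles can therefore be too extreme. Not called were Iroquois (percentile 67.9), NK2 (53.1), Wnt (92.5), FGF (72.7), BMP (62.8), collagen (86.2), potassium channel (15), claudin (37.8), keratin (10.5), Hippo and TEAD (93.8) and retinoid (93.0) genes. With GC matching, however, potassium channel and keratin genes were low (percentile 0 for both) and Hippo and TEAD genes high (97.8), and with CpG matching collagen genes were high (98.3). GC matching dropped the matching on gene length, so changes under it may not come from GC content alone. Single members stood out all the same: the retinoid receptor genes Rara (44.8%) and Rxra (39.3%), Tead1 (44.7%), Col18a1 (36.1%), the cardiac potassium channel genes Kcnh2 (29.8%) and Kcnq1 (25%), and Bmp7 (25.5%). These genes were chosen among the 3 highest of their families after the values were seen.

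The X chromosome was covered far less than the autosomes, in both replicates. Gene length and base composition cannot be the whole account: X genes had a mean coverage of 0.0924 of that of autosomal genes matched on length, CpG-rich 5' ends and GC content (0.163 in replicate 1 and 0.134 in replicate 2). The matched autosomal genes had a mean of 1.71%, below the mean of 4.70% over all protein-coding genes. The ratio of X to autosomal peaks per gene among peaks with −log10 q of at least 5 was 0.281 of that among all peaks. It was 0.273 and 0.236 in the replicates, while no autosome fell below 0.829. This fall cannot decide between fewer marked places of the usual strength and a lower signal along the whole chromosome. The replicated list reaches down to a −log10 q of 0.548, and weak peaks that are mere background would also be lost at the stricter threshold. At that threshold the X ratio itself was 0.0218, resting on 31 X peaks, which is the same observation and not a second test. The X peaks that were called had a median signal close to that of autosomal peaks (3.38 against 3.59). In replicate 1 the medians were 3.49 against 3.55, and in replicate 2 they were 3.36 against 3.58. Places too weak to be called are missing from these medians, so they do not weigh against a lower signal. Whether a lower signal would come from copy number in mixed-sex pools, from the control library or from X inactivation in females was not tested here, and no biological explanation could be tested with 1 group.

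The joint list held fewer peaks than either replicate. Joining of neighbouring peaks cannot be the whole account, since at most 74.7% of a replicate's peaks touched a joint peak, and 74.2% in replicate 2. Replicate peaks that touched none were overlapped by the other replicate 0.0751 times as often as those that touched one (6.43% against 85.6% in replicate 1), and their median signal was 3.16 against 3.82. The joint list was called on the reads of both replicates, so a place with a peak in each is nearly bound to hold a joint peak. The low overlap was thus largely fixed in advance and does not decide why peaks were lost. The lower signal is what would be seen if weak peaks of single replicates were lost when the reads of both are used. Why 17675 replicated peaks did not share 50% of either peak's length with both replicates was not tested; no biological explanation was tested.

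The difference in GC content between peaks and background is no candidate cause for the MEF2 and GATA sites: peak windows were richer in GC, and the shuffled AT-rich consensus sequences had median log2 ratios of −0.54 and −0.28, below 0. For TEAD it could have added to the ratio, which was 0.56 over all windows and 0.55 within GC deciles. The lowest percentile of the 3 within GC deciles was 100, which argues against GC content as the whole cause. The biological explanation, that factors of these families act at the marked places, was not tested here, and related factors share these sites.

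Hypotheses on where such sites lie found no support. Distal peaks within 100 kb of sarcomere genes may hold MEF2 sites more often than those near other genes. Of 561 pairs of a gene and a peak, 7 held a site (1.25%), at percentile 38.2 among random gene lists. A peak near several list genes was counted once for each, here and in the next counts. GATA sites near cardiac transcription factor genes (139 of 467 such pairs, 29.8%) lay at percentile 67.9. The ETS core CCGGAAR near endothelial genes (19 of 267 such pairs, 7.12%) lay at percentile 88.8. Over all 60 pairs of 3 consensus sequences and 20 lists, 4 were called, where chance would call 3. Few sites stand behind the MEF2 value, so a modest difference could be missed.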
